A study of Mus musculus with 8 samples.

How the data were processed

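RNA was measured in white adipose tissue of 8 male mice, 4 wildtype and 4 with an adipocyte-directed deletion of Sel1l, after 5 weeks on a high fat diet. Per the labels' protocols, total RNA was isolated with a column kit, its integrity was checked on a chip, and whole-transcript cDNA was made and labelled with biotin for 1-colour arrays. The deposited values are on a log2 scale, and the submitters' processing notes name RMA, which corrects background, normalizes arrays by quantiles and summarizes probes into probe sets; no version, annotation or filter is given in the sources used here. The log2 scale was read from the values, which run from about 1.72 to 13.9, and is not stated in words. Because RMA makes the arrays' distributions alike, a change of most transcripts in 1 direction would not show in these values, and small changes of dim probe sets are compressed. Quartiles and medians of the 8 arrays were nearly equal, and no gene centring was seen. The medians were 6.05 to 6.08 in WT and 6.10 to 6.14 in Sel1l-/- arrays, without overlap. Direction was taken from the labels, and the deposited values were used without further scaling.

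Probe sets were named through the platform annotation supplied with the values. Of 35556 probe sets, 21218 carried exactly 1 gene symbol, 1881 carried several and 12457 were not in the annotation table, so they are unnamed here. Of the probe sets with 1 gene, 21185 had an Entrez number found in the RefSeq table of assembly GRCm38.p6, and no symbol changed. The build behind the array annotation was not given in the sources used here, so that table was used only for names and for the order of genes, and no coordinates are printed. Each gene was represented by its probe set with the highest mean over all arrays, which left 18820 genes, of which 17434 had 1 probe set and 1386 had several. Genes of the fixed lists that had no probe set of their own were not analysed here. No value was missing and no dim probe set was left out. The table held 540 rows identical to an earlier row, but no tested genes shared all their values.

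Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, prior degrees of freedom 2.60), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The 38 gene lists were fixed before the data were examined, as were the test and the rule for naming genes. They covered ER-associated degradation, ER chaperones, ATF4 and CHOP targets, lipoprotein lipase and its partners, lipid, glucose and mitochondrial metabolism, stress and signalling responses, cell types that adipose tissue can hold, tissues that could be taken with it, and 2 lists on the genotype. The 37 lists with at least 3 measured genes were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Genes adjusted over the list alone were adjusted for the members of that list only. Camera with a correlation estimated from the data called 0 lists, while 2823 single genes had an unadjusted p under 0.05 where chance gives 941. Fry, a rotation test of whether the genes of a list move 1 way on balance, called 4 lists, those of ER chaperones, ATF4 and CHOP targets, ER-associated degradation and endothelial markers. The mean difference of a list between groups is the difference of its mean log2 expression per array. An exact two-sided permutation test of these means cannot go below 0.0286 for 4 against 4 arrays, and its adjusted p was at least 0.181 for each list.

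Named genes were Sel1l and 10 genes fixed in advance (Lpl, Gpihbp1, Angptl4, Lmf1, Syvn1, Hspa5, Adipoq, Lep, Pparg and Nnt), up to 4 members per list past the threshold with the smallest p or, in a list with none, 2 members given as values, and the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap. These made 92 genes. Log2 values are given as mean ± SD, and standard errors are those of limma.

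The titles number the mice 1 to 4 in both groups. Over all genes, the deviations of same-numbered mice from their group means correlated at 0.518, 0.107, 0.363 and 0.524. Since each was over 0.1, the numbers were tried as pairs, from the data and not from a label that says what they share. The main fit had no such block. Mice of different numbers correlated at -0.489 (WT 3 with Sel1l-/- 4) to 0.328 (WT 3 with Sel1l-/- 1). The highest of these lay above the 0.107 of the mice numbered 2, so the pairing is not established. The mouse codes in the labels hold a letter, with WT 1 to 3 on E, WT 4 and Sel1l-/- 1 and 2 on F and Sel1l-/- 3 and 4 on G, and a number, with WT 1, WT 4 and Sel1l-/- 3 on 5, WT 2, Sel1l-/- 1 and Sel1l-/- 4 on 7 and WT 3 and Sel1l-/- 2 on 9. What they stand for was not given in the sources used here, and both were tried as blocks. The other alternatives were median centring, a second quantile normalization, leaving out the dimmest 25% or 50% of genes, the mean of a gene's probe sets, a variance prior with trend and robust settings, array weights, an ordinary test without moderation, a fold change of at least 1.5, and leaving out each array in turn. With the macrophage marker mean as a covariate, and without the 2 arrays with the most immunoglobulin transcript, 2 further fits were chosen after seeing the data.

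The fit was tested on simulated data for 18820 genes in 4 against 4 arrays, in which 50 genes were changed at each of 4 sizes. It recovered 62% of those changed by 0.5 on the log2 scale, 92% at 1, 100% at 2 and 98% at 3, with 8 of 184 calls false (4.35%). In the same data a list shifted by 0.4 was called, and 0 other lists were. In the real arrays, other splits into 4 and 4 called up to 18 lists. The simulation therefore does not show how often list calls are false in the real data.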

Results

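White adipose tissue was profiled on 8 arrays, each from a different male mouse that had eaten a high fat diet for 5 weeks. In 4 mice, Sel1l had been deleted by a Cre recombinase under the adiponectin promoter, which is active in adipocytes, and 4 wildtype (WT) mice served as controls. Sel1l encodes the adapter of the Hrd1 ubiquitin ligase complex, which removes misfolded proteins from the endoplasmic reticulum (ER) for degradation. The knockout mice are called Sel1l-/- here, as in the labels, although the deletion was directed at adipocytes and the tissue also holds other cells. The fat depot was not given in the sources used here. Each array held 35556 probe sets, its median log2 intensity lay between 6.05 and 6.14, and 18820 genes were compared. Correlations between arrays over all probe sets ranged from 0.980 to 0.997, and no 2 arrays held identical values. The number of arrays, 4 per group, limits the precision of each comparison.

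Sel1l was examined first, as a check of the genotype labels. The deleted exons and the places of the probes were not given in the sources used here. Its log2 expression was 10.57 ± 0.07 in WT and 9.78 ± 0.21 in Sel1l-/- mice (SD, n = 4 each), a 1.73-fold lower level (log2 fold change -0.79, standard error 0.10, limma adjusted p = 0.0109). The 4 WT arrays read 10.48, 10.57, 10.58 and 10.65, and the 4 Sel1l-/- arrays read 9.56, 9.78, 9.72 and 10.07, so the groups did not overlap. The call was lost with the letter of the mouse code in the labels as a block (log2 fold change -0.98, adjusted p = 0.151), with the number of that code as a block (-0.80, adjusted p = 0.0813) and in an ordinary test without moderation (adjusted p = 0.0540). Within the mice of letter F, 1 WT and 2 Sel1l-/-, the difference was -0.98, and within the numbers 5, 7 and 9 it was -0.84, -0.75 and -0.80.

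Over all genes, 195 were higher and 129 lower in Sel1l-/- adipose tissue at an adjusted p under 0.05. On each of these 324 genes the 4 Sel1l-/- arrays lay on 1 side of all 4 WT arrays, which passing the threshold nearly requires. Of all genes, 10.3% had such arrays without overlap, where chance gives 2.86%. The change was at least 2-fold in 30 of the higher and 21 of the lower genes. With each array centred on its median, the split became 119 higher and 154 lower, so the excess of higher over lower genes turned with the scaling. The medians of the Sel1l-/- arrays all lay above those of the WT arrays, so centring lowers Sel1l-/- values relative to WT. With the replicate number as a block, 358 genes were higher and 367 lower, and 293 of the 324 genes were among them. The counts moved when 1 array was left out, which also leaves fewer arrays to test. They were 69 higher and 31 lower without WT 1, and 74 and 48 without WT 2. Without WT 3 they were 87 and 55, and without WT 4, 173 and 140. Without Sel1l-/- 1 to 4 in turn they were 89 and 54, 70 and 33, 66 and 36, and 244 and 92. With the letter of the mouse code as a block, 7 genes were higher and 13 lower, and with its number, 8 and 3. The letter held both genotypes only in mice of letter F.

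**Figure D1:**
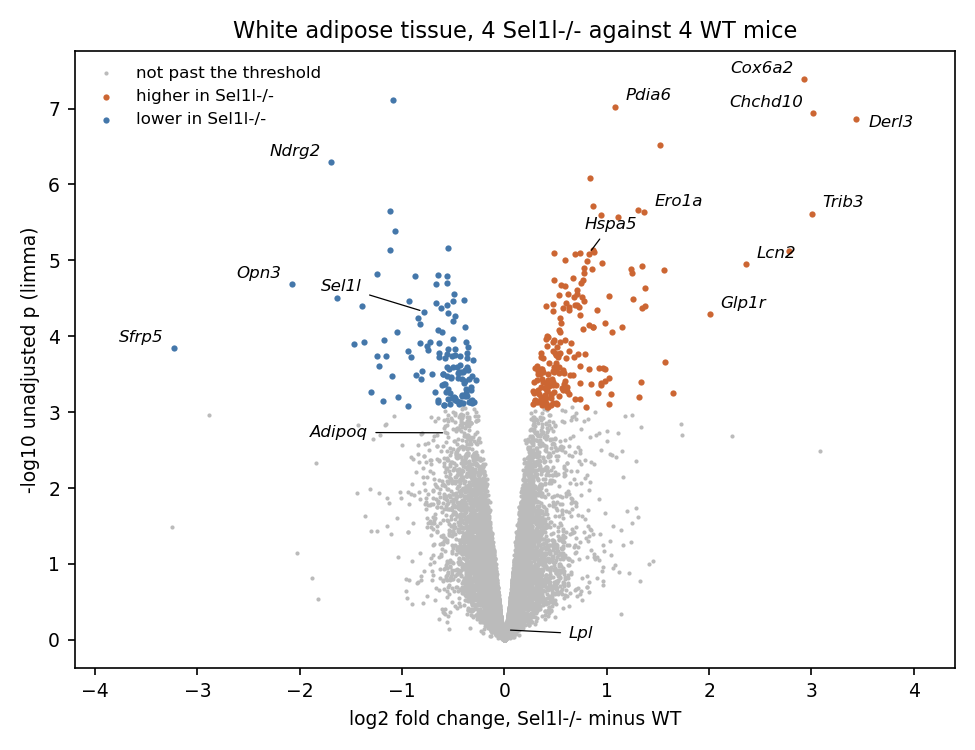
Log2 fold change (Sel1l-/- minus WT, x axis) against -log10 of the unadjusted limma p (y axis) for each of the 18820 genes, with 195 genes higher (orange) and 129 lower (blue) at an adjusted p under 0.05. Derl3, Chchd10, Trib3 and Cox6a2 lie farthest to the right, Sfrp5 and Opn3 lie at the left edge, and Lpl and Adipoq are grey.

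All 26 measured ER chaperones and folding enzymes had positive fold changes. Of these, 12 rose over all genes tested and 20 rose when adjusted over the list alone, with none lower in either count, and the median log2 fold change was 0.42. Pdia6, a protein disulfide isomerase, rose from 9.35 ± 0.10 to 10.42 ± 0.05 (SD, n = 4), or 2.11-fold (adjusted p = 0.000516). Ero1a, the oxidase that keeps disulfide isomerases active, rose 2.57-fold (adjusted p = 0.00334). Hsp90b1, the ER member of the HSP90 chaperones, rose 1.79-fold (adjusted p = 0.00193), Hyou1, a nucleotide exchange factor of the ER lumen, 1.82-fold and Hspa5, the ER chaperone BiP, 1.77-fold (both with adjusted p = 0.00618). The list as a whole was higher by camera (adjusted p = 1.17e-23), but not past the threshold with an estimated correlation between its genes (adjusted p = 0.125). The mean of the list was 0.51 higher in Sel1l-/- mice, 0.43 within letter F, and 0.39, 0.51 and 0.57 within the numbers 5, 7 and 9.

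Known targets of the stress transcription factors ATF4 and CHOP rose as well, 8 of 24 measured members over all genes tested and 11 adjusted over the list alone, which also found 1 lower. Trib3, a pseudokinase, rose 8.03-fold, from 6.39 ± 0.08 to 9.39 ± 0.64 (SD, n = 4; adjusted p = 0.00334). Nupr1, a chromatin-associated stress protein, rose 1.82-fold (adjusted p = 0.00334), Ppp1r15a, the stress-induced subunit that directs dephosphorylation of eIF2α, 1.83-fold (adjusted p = 0.0148), and Fgf21, a metabolic hormone, 1.46-fold (adjusted p = 0.0159). Ppp1r15a lost its call when 1 of 3 arrays was left out (highest adjusted p = 0.0561, without Sel1l-/- 3), and so did Fgf21 with 1 of 2 (0.0590, without WT 2). The list was higher by camera (adjusted p = 5.18e-09) and not past the threshold with an estimated correlation (adjusted p = 0.194). Its mean was 0.50 higher in Sel1l-/- mice, but 0.32 within letter F, against 0.50, 0.54 and 0.56 within the numbers 5, 7 and 9.

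Among the components of ER-associated degradation, the pathway to which Sel1l belongs, 2 of 26 measured members rose over all genes and 7 when adjusted over the list alone, with none lower in either count. Derl3, a derlin thought to take part in moving proteins out of the ER, had the largest rise of any gene past the threshold, from 6.35 ± 0.21 to 9.78 ± 0.47 (SD, n = 4), or 10.8-fold (log2 fold change 3.43, standard error 0.22, adjusted p = 0.000516). Edem1, a lectin-like factor that targets glycoproteins for degradation, rose 1.37-fold (adjusted p = 0.0476), and its call was lost on centring the arrays on their medians (adjusted p = 0.0822) and without any 1 of 7 arrays (up to 0.145, without Sel1l-/- 2). Syvn1, which encodes the ligase Hrd1, had a log2 fold change of 0.22 (standard error 0.09, adjusted p = 0.294). The list was higher by camera (adjusted p = 2.45e-08), and the adjusted p with an estimated correlation was 0.194. Its median log2 fold change was 0.14. Its mean was 0.29 higher in Sel1l-/- mice, 0.32 within letter F, and 0.25, 0.33 and 0.28 within the numbers 5, 7 and 9. Without Derl3 the mean of the other 25 genes was 0.16 higher (standard error 0.03).

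**Figure D2:**
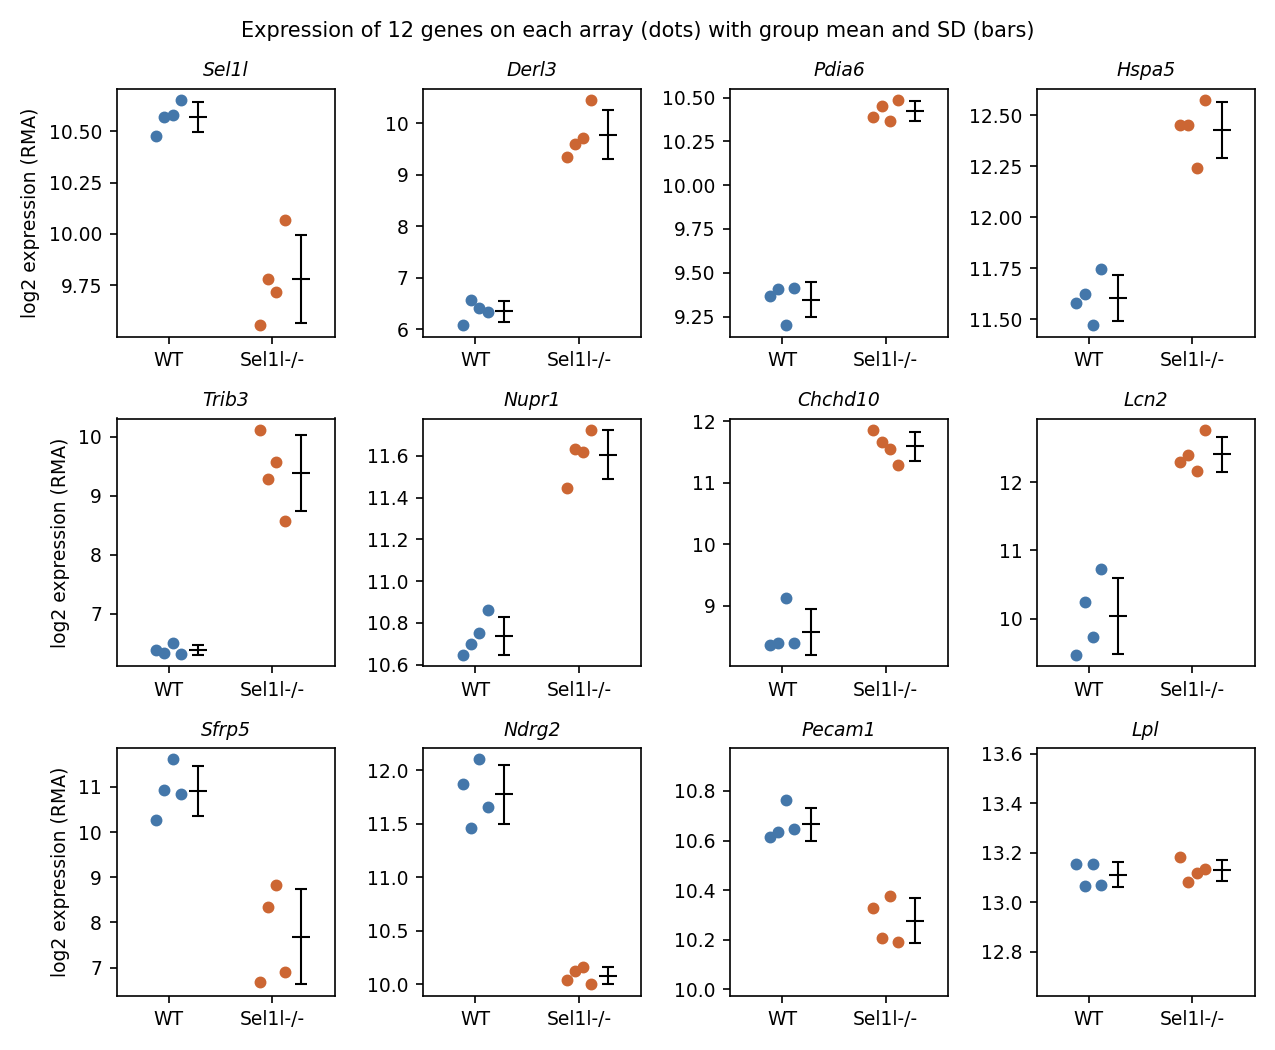
Log2 expression (y axis) of 12 genes on each of the 4 WT (blue) and 4 Sel1l-/- (orange) arrays, with dots for arrays and bars for the group mean ± SD; the y axes differ between panels and do not start at 0. In all panels but that of Lpl the orange and blue dots do not overlap, and Lpl lies near 13.1 in both groups.

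The series title names lipoprotein lipase, the enzyme that releases fatty acids from circulating triglyceride, as the question of the study. Its transcript, Lpl, was 13.11 ± 0.05 in WT and 13.13 ± 0.04 in Sel1l-/- mice (SD, n = 4), a log2 fold change of 0.02 (standard error 0.05, adjusted p = 0.912) that was -0.02 with the arrays centred on their medians. The mean of Lpl lay at percentile 99.9 of the genes tested, near the top of the scale. Whether differences are compressed there was not tested, so a small change of Lpl cannot be excluded. None of the 19 measured genes of lipoprotein lipase and its partners passed the threshold, over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.794 (0.602 with the replicate block). The list mean was lower in each of the 4 same-numbered pairs, by 0.04 to 0.08, where 19 of the 38 lists had the same sign in all pairs and chance gives 12.5%. Gpihbp1, which carries the enzyme to the capillary lumen, had a log2 fold change of -0.51 (adjusted p = 0.223), and Angptl4, its secreted inhibitor, one of 0.41 (adjusted p = 0.512), which was -0.29 with the letter of the mouse code as a block. Lmf1, needed for the folding of the enzyme in the ER, had a log2 fold change of 0.02 (adjusted p = 0.946), and -0.02 with the arrays centred. Apoc2, the activator of the enzyme, had one of 0.52 (adjusted p = 0.0982, but 0.0367 without WT 2). The sorting receptor Sort1 had one of -0.40 (adjusted p = 0.197, but 0.0339 with the replicate block). These arrays measure transcripts and say nothing of protein level or enzyme activity.

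Other lists of lipid metabolism held few genes past the threshold. None of 19 lipolysis and lipid droplet genes passed over all genes and 1 rose adjusted over the list alone. The list's median and camera test were negative and its mean was positive (median -0.07, mean 0.04, camera adjusted p = 0.857). Plin5, a lipid droplet coat protein, had a log2 fold change of 0.65 (adjusted p = 0.0617). It passed with array weights (adjusted p = 0.0320) and without Sel1l-/- 1 or Sel1l-/- 4 (0.0265 and 0.0455). Hilpda, an inhibitor of the lipase Pnpla2, had one of 0.44 (adjusted p = 0.135). None of 17 genes of fatty acid uptake and triglyceride synthesis passed in either count (camera adjusted p = 0.436), with Mogat2 at -0.51 (adjusted p = 0.315) and Gpam at -0.43 (adjusted p = 0.371). Of 19 genes of de novo lipogenesis none passed over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.569). Thrsp, a lipogenic nuclear protein, had a log2 fold change of -1.17 (adjusted p = 0.0659, but 0.00953 with the replicate block), and Pnpla3 one of -0.59 (adjusted p = 0.220). In the cholesterol list 1 of 15 genes rose, Lss, lanosterol synthase, by 1.73-fold (adjusted p = 0.0232), and 2 rose adjusted over the list alone. Lss kept its call in 3 of the 8 fits that left out 1 array (up to 0.0753, without Sel1l-/- 3). The camera adjusted p of the list was 0.318, but 0.0435, higher, without Sel1l-/- 2.

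Fatty acid oxidation genes were higher as a list (21 measured, camera adjusted p = 0.0338, but 0.793 with an estimated correlation), but 1 of them rose over all genes and 2 adjusted over the list alone. The member that rose was Hadha, a subunit of the mitochondrial trifunctional protein, by 1.22-fold (adjusted p = 0.0404). The list's call was also lost with the replicate block (adjusted p = 0.0576), with the letter block (0.0937), on leaving out the dimmest 25% or the dimmer 50% of genes (0.0618 and 0.131), and without WT 1, WT 2, WT 4, Sel1l-/- 1 or Sel1l-/- 3 (0.102, 0.139, 0.0561, 0.0780 and 0.0985). Hadha lost its call with the replicate block (adjusted p = 0.0607), with the arrays centred (0.0901) and without any 1 of 7 arrays (up to 0.129, without Sel1l-/- 2). The respiratory chain list was lower (27 measured, none past the threshold in either count, median log2 fold change -0.08, camera adjusted p = 0.0268). That call was lost with an estimated correlation (adjusted p = 0.890), with the macrophage marker mean as a covariate (0.520) and without WT 1, WT 3, Sel1l-/- 3 or Sel1l-/- 4 (0.102, 0.234, 0.0551 and 0.148), and the direction turned with the letter block (0.0956). Its members Ndufb8 and Sdhb had log2 fold changes of -0.21 (adjusted p = 0.313, and 0.02 with the letter block) and 0.20 (adjusted p = 0.203). Of 17 genes of thermogenic adipocytes none passed over all genes and 2 were higher adjusted over the list alone (camera adjusted p = 0.355), with Cox8b at 0.85 (adjusted p = 0.114) and Elovl3 at 0.74 (adjusted p = 0.0980).

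The insulin and glucose handling list was lower (21 measured, median log2 fold change -0.15, camera adjusted p = 0.0387, but 0.744 with an estimated correlation), with 1 member higher and 1 lower, over all genes and adjusted over the list alone. Ldhb, a lactate dehydrogenase subunit, fell to a 1.47-fold lower level (adjusted p = 0.0287), and Pfkl, a phosphofructokinase of glycolysis, rose 1.24-fold (adjusted p = 0.0328). Both were lost without any 1 of 7 arrays (up to 0.0811 without Sel1l-/- 3 for Ldhb, and 0.114 without Sel1l-/- 2 for Pfkl), and Pfkl also with the arrays centred (0.0616). The dimmer probe set of Ldhb, not used in the fit, fell more, with a log2 fold change of -0.85 against -0.56. The list's adjusted p was 0.0878 with the arrays centred, 0.0618 and 0.0648 on leaving out the dimmest 25% or the dimmer 50% of genes, and 0.123 with the macrophage marker mean as a covariate. It was 0.124, 0.0711, 0.0539, 0.0551 and 0.0777 without WT 1, WT 3, Sel1l-/- 2, Sel1l-/- 3 and Sel1l-/- 4, and its direction turned with the letter block (0.936).

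Of the 8 largest rises past the threshold, 5 lay outside the fixed lists. Chchd10, a protein of the mitochondrial intermembrane space, rose 8.11-fold (log2 fold change 3.02, standard error 0.19, adjusted p = 0.000516), and Cox6a2, the heart and muscle form of a cytochrome c oxidase subunit, rose 7.59-fold (log2 fold change 2.92, standard error 0.16, adjusted p = 0.000516). Glp1r, the receptor of glucagon-like peptide 1, rose at least 4.03-fold (adjusted p = 0.0116, and 0.0503 without WT 1). Its WT mean of 4.30 ± 0.46 (SD, n = 4) lay below the lower quartile of all probe sets on each array (4.33 to 4.37). It is not shown to be above background. The unnamed transcript A830018L16Rik rose 6.87-fold (adjusted p = 0.00618), and Trim66 rose 3.13-fold (adjusted p = 0.0404). Trim66 kept its call in 1 of the 8 fits that left out 1 array (adjusted p up to 0.129, without Sel1l-/- 2). The call was also lost with the arrays centred on their medians (0.0502). Derl3, Chchd10 and Cox6a2 were the 3 named genes still past the threshold with the letter of the mouse code as a block (adjusted p = 0.0390, 0.0332 and 0.0164).

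The largest fall was that of Sfrp5, a secreted antagonist of Wnt signalling made by adipose tissue, from 10.91 ± 0.55 to 7.69 ± 1.06 (SD, n = 4), or 9.38-fold (adjusted p = 0.0216, and up to 0.0666 without WT 2). Opn3, a non-visual opsin, was 4.23-fold lower (adjusted p = 0.00817), Ndrg2, a protein of the NDRG family, 3.23-fold lower (adjusted p = 0.00137) and Car1, a carbonic anhydrase, 3.11-fold lower (adjusted p = 0.00992). Ifi27l2a was 2.78-fold lower (adjusted p = 0.0200), Trhde, a peptidase, 2.63-fold lower (adjusted p = 0.0103), Smoc1, a matricellular protein, 2.60-fold lower (adjusted p = 0.0195) and Ranbp3l at least 2.46-fold lower (adjusted p = 0.0400). The Sel1l-/- mean of Ranbp3l, 4.04, lay below the lower quartile of all probe sets. Of the 8 fits that left out 1 array, Ifi27l2a kept its call in 5 (adjusted p up to 0.0698, without WT 1). Smoc1 and Ranbp3l kept theirs in 3 and 1 (up to 0.0687 and 0.114, without Sel1l-/- 2). Of all 42 named genes past the threshold, 20 stayed past it in all 8 fits that left out 1 array, among them Sel1l, Derl3, Pdia6, Hspa5, Trib3, Chchd10, Lcn2, Opn3 and Ndrg2. With the number of the mouse code as a block, 35 of the 42 lost the call, among them Sel1l, Hspa5 (adjusted p = 0.0600), Trib3 (0.0544), Lcn2 (0.0614) and Opn3 (0.0571). The log2 fold changes of these examples moved little. With that block they were -0.80 for Sel1l, 0.80 for Hspa5, 3.03 for Trib3, 2.30 for Lcn2 and -2.06 for Opn3. Without it they were -0.79, 0.82, 3.01, 2.36 and -2.08. With the letter as a block 39 lost the call, and Derl3, Chchd10 and Cox6a2 kept it. The number that lost the call was 22 without WT 1, 19 without WT 2, 13 without WT 3, 9 without WT 4, and 14, 16, 19 and 8 without Sel1l-/- 1 to 4. In the ordinary test without moderation 23 of the 42 lost it, among them Sel1l and Opn3. Without both WT 2 and Sel1l-/- 4, 23 lost it, among them Opn3 and Rbp4.

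All 18 measured adipocyte markers had negative fold changes, of which 1 fell over all genes and 5 adjusted over the list alone. Rbp4, the retinol binding protein secreted by adipocytes, was 1.59-fold lower (adjusted p = 0.00817). Adipoq, the hormone adiponectin, had a log2 fold change of -0.56 (standard error 0.13, adjusted p = 0.0753, but 0.0204 with the replicate block), and Lep, leptin, one of -0.11 (adjusted p = 0.682). Pparg, the master regulator of adipocyte differentiation, had a log2 fold change of -0.18 (adjusted p = 0.606), and 0.18 with the letter block. The list was lower by camera (median log2 fold change -0.18, adjusted p = 9.60e-06), not past the threshold with an estimated correlation (adjusted p = 0.793) or the letter block (0.654). The mean difference of the list was -0.35, but -0.03 within letter F, and -0.16, -0.38 and -0.45 within the numbers 5, 7 and 9. Sel1l-/- 4, with the lowest adipocyte mean of the 8 arrays, also had the highest macrophage mean, 0.69 above the WT mean.

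All 19 endothelial markers had negative fold changes too. Of these, 3 fell over all genes and 16 adjusted over the list alone. Pecam1, an adhesion protein of endothelial junctions, was 1.31-fold lower (adjusted p = 0.0290), Eng, endoglin, 1.30-fold lower (adjusted p = 0.0195) and the water channel Aqp1 1.37-fold lower (adjusted p = 0.0322). Pecam1 and Aqp1 lost their calls without any 1 of the 8 arrays (up to 0.102 and 0.0986), and Eng without any 1 of 5 (up to 0.0765, without Sel1l-/- 2). The list had a median log2 fold change of -0.38 and was lower by camera (adjusted p = 1.20e-12), with an adjusted p of 0.294 with an estimated correlation. The mean difference was -0.38, against -0.26 within letter F and -0.27, -0.35 and -0.49 within the numbers 5, 7 and 9.

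Fibroblast and preadipocyte markers were lower as a list (13 measured, none past the threshold over all genes and 3 lower adjusted over the list alone, median log2 fold change -0.29, camera adjusted p = 0.00120), with an adjusted p of 0.603 with an estimated correlation and 0.197 with the letter block. Gsn had a log2 fold change of -0.45 (adjusted p = 0.0970, but 0.0277 with the replicate block) and Dlk1 one of -0.35 (adjusted p = 0.159). Markers of the mesothelium, the lining of visceral fat, had negative fold changes in all 10 measured genes, none past the threshold over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.00910, and 0.793 with an estimated correlation). Wt1 had a log2 fold change of -0.44 (adjusted p = 0.108, but 0.0382 with the replicate block) and Upk1b one of -0.60 (adjusted p = 0.261, but 0.0204 with that block). The mesothelial call was lost without WT 3 (0.133) or Sel1l-/- 4 (0.103), with array weights (0.0558) and with the macrophage mean as a covariate (0.190), and its direction turned with the letter block (0.589).

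**Figure D3:**
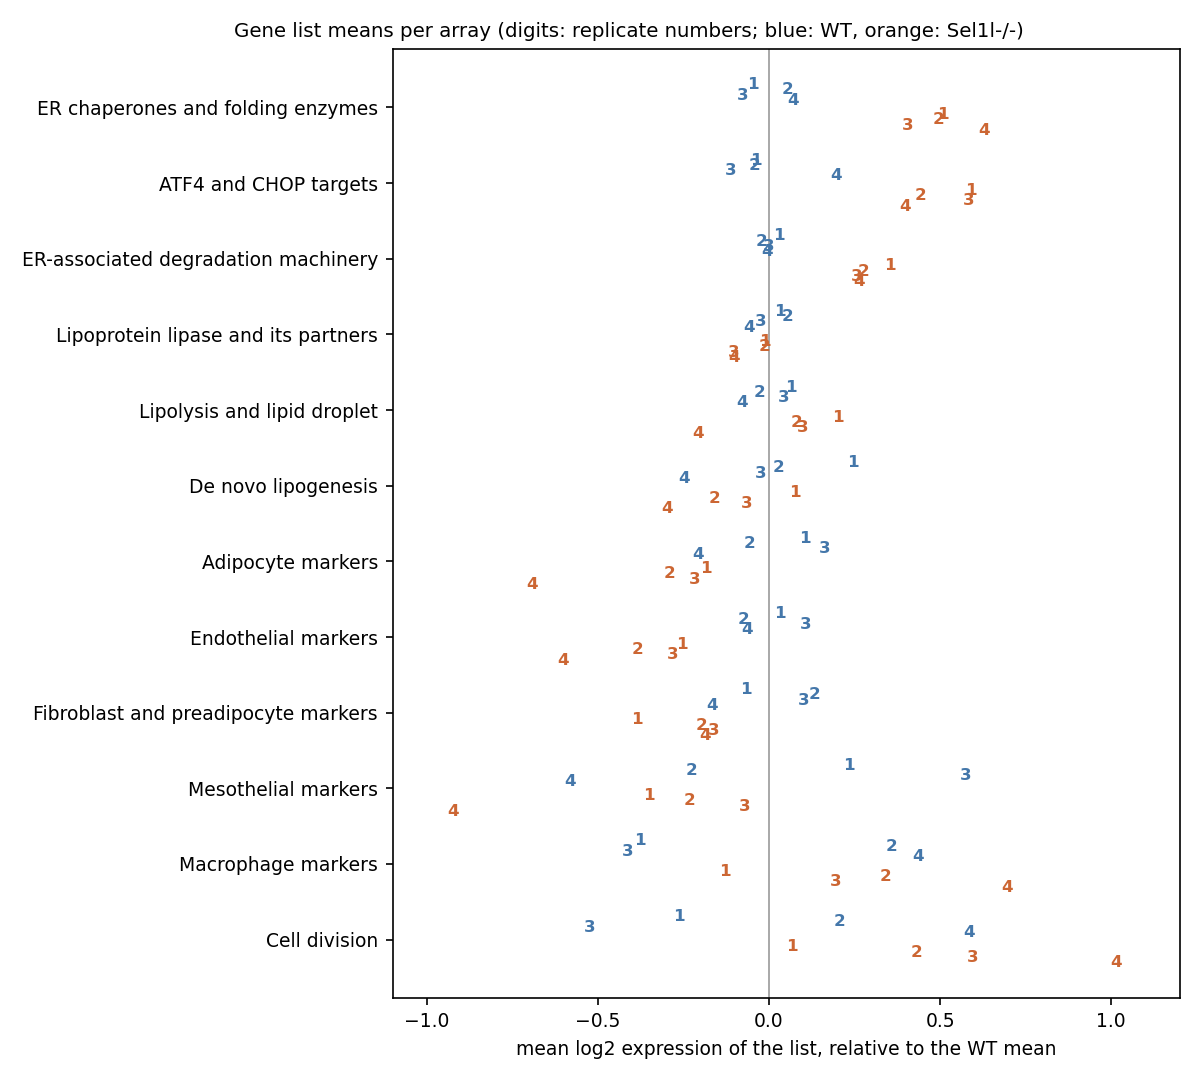
Mean log2 expression of 12 gene lists on each array relative to the WT mean of the list (x axis), where each digit is the replicate number of a WT (blue) or Sel1l-/- (orange) mouse, spread vertically for legibility. The groups lie apart for the ER chaperone, ATF4 and CHOP, ER-associated degradation and endothelial lists, and overlap for the macrophage and cell division lists.

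The 29 macrophage markers had a mean difference of 0.28 (standard error 0.29, camera adjusted p = 0.0748), with a range from -0.41 to 0.43 over the WT arrays and from -0.13 to 0.69 over the Sel1l-/- arrays. The list passed as higher with the replicate block (adjusted p = 0.00152), with the arrays centred (0.00898) and without WT 2, WT 4 or Sel1l-/- 1 (0.00378, 0.00670 and 0.00392). With the letter block it passed as lower (0.0401). Over all genes 1 of them fell, as it did adjusted over the list alone. This was Retnla, a marker of alternatively activated macrophages, at a 1.68-fold lower level (adjusted p = 0.0224). It kept the call in 3 of the 8 fits that left out 1 array (up to 0.0690, without WT 2). Of 9 genes of MHC class II presentation none passed in either count (camera adjusted p = 0.945, but 0.000529 and 0.00664, lower, with the letter block and the macrophage covariate), with Flt3 at 0.27 (adjusted p = 0.629, and -0.06 with the letter block) and Ccr7 at 0.11 (adjusted p = 0.701). Of 15 T and NK cell markers 1 fell in either count, the T cell adhesion receptor Cd2, to a 1.57-fold lower level (adjusted p = 0.0456). Cd2 kept the call in 1 of the 8 fits that left out 1 array (up to 0.119, without WT 2). The camera adjusted p of the list was 0.489, but 0.0183, lower, without WT 3. B cell markers were lower as a list (10 measured, none past the threshold in either count, camera adjusted p = 0.0270), with Fcmr at -0.50 (adjusted p = 0.128, but 0.0275 with the replicate block) and Cr2 at -0.20 (adjusted p = 0.281). That call was lost with an estimated correlation (adjusted p = 0.744), with the arrays centred (0.0686), with the letter block (0.936), on leaving out the dimmest 25% or the dimmer 50% of genes (0.0953 and 0.536), and without WT 2, Sel1l-/- 1 or Sel1l-/- 3 (0.0954, 0.0847 and 0.0551). Of 20 granulocyte and mast cell markers none passed in either count (camera adjusted p = 0.489), with Kit at -0.52 (adjusted p = 0.153, but 0.0400 with the replicate block) and Epx at 0.17 (adjusted p = 0.450).

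The 18 measured genes of cell division all had positive fold changes, with a median of 0.56, yet none passed the threshold over all genes or adjusted over the list alone. Aurkb and Pbk, kinases of mitosis, had log2 fold changes of 0.55 (adjusted p = 0.325) and 0.57 (adjusted p = 0.313), which were -0.08 and -0.22 with the letter block. Camera placed the list higher (adjusted p = 7.16e-06), but its genes were correlated at an estimated 0.932, and the adjusted p with that correlation in place of the preset one was 0.793. With the letter block the list was lower (adjusted p = 0.00570). Within each group the lowest array in this list was also the lowest in the macrophage list (WT 3 and Sel1l-/- 1), and the highest was the highest there (WT 4 and Sel1l-/- 4).

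Stress and signalling lists other than those of the ER mostly held single genes past the threshold. In the inflammatory list 1 of 26 genes rose over all genes and 2 adjusted over the list alone (camera adjusted p = 0.318, but 0.0499 and 0.0340, higher, without WT 2 and WT 4). The gene past the threshold was Lcn2, lipocalin 2, an acute phase protein that binds siderophores, at a 5.12-fold higher level (from 10.05 ± 0.56 to 12.40 ± 0.26, SD, n = 4, adjusted p = 0.00729). Sqstm1, an autophagy receptor, rose 1.38-fold (adjusted p = 0.0107) as the 1 gene past the threshold among 20 of autophagy and lysosome in either count (camera adjusted p = 0.569, but 0.0211, lower, with the letter block). Among 20 NRF2 targets 1 fell over all genes, Nqo1, a quinone reductase, to a 1.25-fold lower level (adjusted p = 0.0452, 0.0600 with the replicate block and over 0.05 without any 1 of the 8 arrays, up to 0.146), and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.602). Among 28 collagen and matrix genes 1 fell in either count, Ccn2, a matricellular growth factor, to a 1.92-fold lower level (adjusted p = 0.0228). Ccn2 kept the call in 3 of the 8 fits that left out 1 array (up to 0.0797, without Sel1l-/- 2). The camera adjusted p of the list was 0.240. That list passed as lower with array weights (0.0341), the letter block (7.30e-07) and the macrophage covariate (3.56e-05). It did so too without WT 1 or Sel1l-/- 4 (0.00347 and 0.00583). None of 18 interferon response genes passed in either count (camera adjusted p = 0.240, but 0.0336 and 0.00525, lower, without WT 1 and Sel1l-/- 3), with Ifit2 at -0.26 (adjusted p = 0.337) and Ifih1 at -0.21 (adjusted p = 0.485).

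None of 17 hypoxia targets passed in either count (camera adjusted p = 0.945, median 0.02 and mean -0.06), with Adm at -0.53 (adjusted p = 0.142) and Pgk1, which is uncertain because its probe sets gave nearly identical values, at 0.25 (adjusted p = 0.160). The mean of the hypoxia list was lower in each of the 4 same-numbered pairs, with differences from -0.067 to -0.047. Of the 38 lists, 19 had the same sign in all pairs. Circadian clock genes were lower as a list by camera, but 4 of the 15 measured had positive fold changes (none past the threshold over all genes, 1 higher and 3 lower adjusted over the list alone, median log2 fold change -0.42, camera adjusted p = 0.0387, but 0.793 with an estimated correlation). Hlf and Per1, 2 clock transcription regulators, had log2 fold changes of -0.64 (adjusted p = 0.0608, but 0.0409 with the replicate block) and -0.48 (adjusted p = 0.0629, but 0.0330 with that block). Arntl, Nfil3 and Npas2, chosen after their values were seen, went the other way (adjusted p = 0.0844, 0.240 and 0.352). The log2 fold changes of Nfil3 and Npas2 were 0.72 and 0.61, and that of Arntl was larger. The clock call was also lost with the arrays centred (adjusted p = 0.132), after a second quantile normalization (0.0524), on leaving out the dimmest 25% of genes (0.0618), with the number block (0.0689) and with the macrophage marker mean as a covariate (0.123). It was lost too without WT 1, WT 3 or any Sel1l-/- mouse (0.105, 0.129, and from 0.0520 upward without each Sel1l-/- mouse), and its direction turned with the letter block (0.654). The hour at which the tissue was taken was not given in the sources used here. Of 14 glucocorticoid targets 1 rose and 1 fell over all genes, and 2 rose and 2 fell adjusted over the list alone (median -0.05, mean 0.16, camera direction up with adjusted p = 0.945). The gene that fell was Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at a 1.42-fold lower level (adjusted p = 0.0102), and the one that rose was Lcn2. Of 13 immediate early genes 1 fell in either count, Jun, a subunit of AP-1, to a 1.45-fold lower level (adjusted p = 0.0472, 0.0700 with the replicate block and over 0.05 without any 1 of the 8 arrays; list adjusted p = 0.945).

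Lists for other tissues and for the genetic background did not pass the threshold. Skin and mammary epithelium markers (12 measured, none past the threshold in either count, camera adjusted p = 0.569) included Trf at -0.32 (adjusted p = 0.254) and Krt10 at -0.10 (adjusted p = 0.614). Epididymis and testis markers (11 measured, none in either count, camera adjusted p = 0.741) included Defb20 at 0.12 (adjusted p = 0.410) and Lcn9 at -0.09 (adjusted p = 0.486). Among 14 skeletal muscle markers 1 rose in either count, Casq1, the calcium store protein calsequestrin 1, by 2.22-fold (adjusted p = 0.0148, and up to 0.0610 without WT 1), while the list's median was -0.01, its mean -0.00302 and its camera direction up (adjusted p = 0.985). Of 2 red blood cell markers measured, too few for a list test, neither passed over all genes and 1 was lower adjusted over the list alone, with Alas2 at -0.72 (adjusted p = 0.206) and Slc4a1 at -0.19 (adjusted p = 0.591). The 3 Schwann cell markers did not pass in either count (camera adjusted p = 0.569), with S100b at 0.33 (adjusted p = 0.455) and Sox10 at 0.02 (adjusted p = 0.946). Of 7 genes near Adipoq on its chromosome none passed in either count (camera adjusted p = 0.485), with Fetub at 0.17 (adjusted p = 0.423) and Kng1 at 0.20 (adjusted p = 0.461). The mice were on a mixed C57BL/6N and C57BL/6J background, and of 3 genes known to differ between these none passed in either count (camera adjusted p = 0.436). Among them Nnt, a mitochondrial transhydrogenase, had a log2 fold change of -0.47 (adjusted p = 0.246), while its dimmer probe set had one of 0.03. Crb1 had one of -0.12 (adjusted p = 0.600), and its mean lay at percentile 8.94 of the genes tested, where changes are compressed. The list test looks for a shift in 1 direction, and no direction was set for these genes. It therefore cannot show whether the groups differed in background.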

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

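In this part, the macrophage covariate was added after the data had been seen, and the tests of plasma cells, of the list counts in splits that part the pairs, of a smaller share of adipocytes, and of the mouse code letter on the adipocyte and endothelial lists were chosen after their results had been seen. Among the 35 ways to part the 8 arrays into 4 and 4, only the real split gave as many as 195 genes in 1 direction, or as many as 129. The highest count of any other split was 1, but the other splits mix the genotypes, so a real difference would itself lower their counts. If the mice are not paired, 1 of 35 is a share under 0.05 and the lowest that these 35 splits can give. Of these splits, 8 part every same-numbered pair of mice, and among them the real one called 324 genes (725 with the replicate block) and the highest other 0 in both fits. These 8 splits are too few for a share under 0.05. The remaining splits keep some same-numbered mice together. For the 13 gene lists past the threshold chance cannot be excluded, since 8 of 35 splits called as many lists and 1 of them called 18. Among the 8 that part every pair, too few for a share under 0.05, the highest other called 11 lists against 13 for the real one. With the replicate block both called 13. The split with 18 lists set WT 4, Sel1l-/- 1, 2 and 4, which hold all mice of letter F, against the rest, and with the letter as a block the real comparison called 9 lists. Of these, 5 were among the 13, with cell division in the opposite direction, and 4 were not (autophagy, collagens, macrophages and MHC class II).

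The ER chaperone and the ATF4 and CHOP lists were higher in Sel1l-/- tissue, with mean shifts of 0.51 (standard error 0.06) and 0.50 (standard error 0.08). Plasma cells are rich in ER chaperones, but with the mean of 12 plasma cell markers as a covariate the shifts were 0.53 (standard error 0.05) and 0.48 (standard error 0.09), and with the macrophage mean they were 0.46 (standard error 0.04) and 0.49 (standard error 0.10), which argues against either cell type as the whole cause. With the letter of the mouse code as a block the shifts were 0.43 (standard error 0.11) and 0.32 (standard error 0.11), but handling in code order cannot be told apart from genotype, since the codes put all WT mice before all Sel1l-/- mice, also within letter F. A stress response of adipocytes that lack Sel1l stays open and was not tested, since whole tissue does not show in which cells the transcripts rose.

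Adipocyte and endothelial markers were lower in Sel1l-/- tissue, with shifts of -0.35 (standard error 0.14, or 0.06 over the 4 pairs) and -0.38 (standard error 0.09, or 0.06 over the pairs), negative in all 4 pairs. With the macrophage mean as a covariate the shifts were -0.22 (standard error 0.08) and -0.31 (standard error 0.06). The macrophage marker mean thus did not account for the whole of either shift. That mean is an imprecise measure of macrophage content, so dilution by macrophages cannot be excluded. A smaller share of adipocytes alone would raise the markers of the other cell types, and the endothelial shift of -0.38 goes the other way. Handling in letter order cannot be told apart from genotype here, because with the letter as a block the adipocyte shift was -0.0302 (standard error 0.23) and the endothelial shift -0.26 (standard error 0.17), and the code order follows genotype. Lower transcript levels per cell, or fewer cells of both types, stay open and were not tested.

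The cell division list was higher in Sel1l-/- tissue with a shift of 0.53 (standard error 0.32, or 0.20 over the 4 pairs, all positive) that moved with the macrophage markers. With the macrophage mean as a covariate the shift was 0.24 (standard error 0.12), less than before but about 2 standard errors from 0. Macrophage content may thus account for part of it, and this cannot be told apart from genotype with 4 mice per group. No other biological explanation was tested for this list.

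Single arrays lay far from the other 3 of their group in 12 of 260 sets of 4 values tested, where chance alone gives about 13. Among genes in WT mice, Hyou1 read 9.60 in WT 4 (the others 9.47 to 9.49), Hilpda 7.06 in WT 4 (6.74 to 6.78), Ldhb 8.66 in WT 4 (8.34 to 8.39), Sdhb 9.98 in WT 1 (9.86 to 9.87), Alas2 7.55 in WT 2 (8.46 to 8.60) and Chchd10 9.13 in WT 3 (8.37 to 8.40). Among genes in Sel1l-/- mice, Gpam read 10.76 in Sel1l-/- 4 (10.11 to 10.18), and in Sel1l-/- 1 Elovl3 read 5.73 (4.93 to 4.95), Sqstm1 12.38 (12.27 to 12.28) and Retnla 11.32 (11.73 to 11.79). The cholesterol list mean was -0.24 in WT 3 (0.05 to 0.10 in the others), and the fibroblast list mean was -0.38 in Sel1l-/- 1 (-0.20 to -0.16), both relative to the WT mean.

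Probe sets outside the comparison of named genes also passed the threshold when all 35556 were tested together. Of 1881 probe sets with several genes 9 passed, 7 higher and 2 lower. Of 12457 not in the annotation 75 passed, 69 higher and 6 lower.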

How the results depend on the processing

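The fits with the macrophage covariate and without WT 2 and Sel1l-/- 4, the arrays with the most immunoglobulin transcript, were chosen after seeing the data. All 324 genes past the threshold kept their sign in each of the settings in which they were tested. Their arrays did not overlap between groups, so fits that block, weight or leave out arrays could not have turned the sign. The counts of genes higher and lower were 195 and 129. They became 119 and 154 with arrays centred on their medians (the median of all genes moved to -0.05), 347 and 219 with array weights, 87 and 37 in the ordinary test without moderation, 358 and 367 with the replicate block, 7 and 13 with the letter block (4 of these 20 genes shared with the 324), 8 and 3 with the number block, 94 and 55 at a fold change of at least 1.5, 309 and 229 with the macrophage covariate, and 70 and 26 without the 2 arrays, where fewer arrays were tested. Leaving out 1 array at a time gave 66 to 244 higher and 31 to 140 lower genes, with the arrays that moved them named in the report. A second quantile normalization, leaving out dim genes, averaging probe sets and a trended robust prior kept both counts within a factor of 1.5. The log2 fold change of Sel1l was -0.79 and lost its call in the ordinary test (-0.79, adjusted p = 0.0540), with the letter block (-0.98) and with the number block (-0.80). It ranged from -0.88 to -0.71 over single arrays left out. The 13 lists past the threshold became 0 with an estimated correlation (4 at an unadjusted p under 0.05), 4 by fry and 7 without the 2 arrays, and 9 to 14 over single arrays left out. None of the 42 named genes past the threshold, all among the 324, turned sign, and 11 of those not past it did in some setting. With arrays centred, Lpl was -0.0235, Lmf1 -0.0246 and Sox10 -0.0253; Sox10 was -0.0068 after requantiling and -0.0087 without the 2 arrays. With the letter block Angptl4 was -0.29, Pparg 0.18, Ndufb8 0.0153, Pbk -0.22, Aurkb -0.0760, Flt3 -0.0580, Sox10 -0.0813, Fetub -0.0146 and Crb1 0.0327. Of the 13 lists past the threshold, those that turned direction with that block were the respiratory chain (adjusted p = 0.0956), insulin and glucose handling (0.936), cell division (0.00570), circadian clock (0.654) and mesothelial markers (0.589). Among lists not past the threshold, the macrophage list and the autophagy and lysosome list turned from higher to lower with it as well. Over single arrays left out, Lpl ranged from -5.22e-06 to 0.0347, Lmf1 from -0.0149 to 0.0610 and Sox10 from -0.0198 to 0.0693. The replicate block changed no other call of a named gene or list than those given in the report, which include the macrophage list that it gained. Centring lowers the Sel1l-/- arrays relative to WT. Apart from that, and except where fewer arrays or fewer genes were tested, the cause of these changes was not tested. Dim probe sets lie near background on these arrays, so that small changes there are compressed.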

Other observations

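The gene lists and values of this part were all chosen after the data had been seen. Some genes of the secretory pathway rose in Sel1l-/- tissue. The lists were drawn up after members had been seen to rise, so that no list test is given. They share Sec61a1, Sec61b and Ssr1 with the chaperone list of the report, and Nars, Cars, Mthfd2, Phgdh and Psat1 with its ATF4 and CHOP list. Of these, Sec61a1 and Nars rose. Of 42 measured genes of ER translocation and N-glycosylation all had positive fold changes and 12 rose, among them Stt3a, a catalytic subunit of oligosaccharyltransferase, with a log2 fold change of 0.59 (adjusted p = 0.00712) and Sec61g, a subunit of the translocon, with a 1.54-fold higher level (adjusted p = 0.00972). Of 35 genes of COPI and COPII coats and cargo receptors 10 rose and none fell, among them Kdelr2 and Kdelr3, receptors that return ER proteins from the Golgi, with log2 fold changes of 0.54 and 0.68 (adjusted p = 0.00978 and 0.0235).

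Of 19 cytosolic aminoacyl-tRNA synthetase genes 4 rose (Eprs, Iars, Nars and Sars), Eprs by 1.72-fold (adjusted p = 0.0102). Of 16 genes in a list of mitochondrial chaperones and proteases that also held Chchd10, 11 had positive fold changes and 5 rose (Hspe1, Hspa9, Grpel1, Lonp1 and Chchd10), with Lonp1, a matrix protease, at 1.71-fold (adjusted p = 0.00767) and Grpel1, a cofactor of the matrix HSP70, at 1.68-fold (adjusted p = 0.00817). Of 13 genes of serine and one-carbon synthesis 9 had positive fold changes, with a list median of 0.07, and 2 rose. These were Aldh1l2, by 2.60-fold (adjusted p = 0.00861), and Pck2, by 2.39-fold (adjusted p = 0.0102), both mitochondrial enzymes.

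Derl3 and Chchd10, at 10.8-fold and 8.11-fold 2 of the largest rises, lie near each other on chromosome 10 in the order of the RefSeq table. Between them lie Smarcb1 (log2 fold change 0.30, adjusted p = 0.160) and Mmp11 (0.73, adjusted p = 0.0448). The measured gene before Derl3 is Mif (0.48, adjusted p = 0.0103), which has several probe sets, and before that Gstt2 (0.05, adjusted p = 0.928). After Chchd10 come Vpreb3 (0.19, adjusted p = 0.402) and Gm5134 (-0.02, adjusted p = 0.922). Over all chromosomes 5 pairs of neighbouring genes were both higher, against a mean of 1.87 and a highest of 9 over 1000 random orders. Of the 50 measured genes nearest to Sel1l on its chromosome 0 passed the limma threshold, where 1.72% of all genes passed, and 9 had an unadjusted p under 0.05 (18.0%, against 15.0% of all genes).

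The first principal component held 42.2% of the variance and the second 22.6%. On the first, WT 3 and WT 1 lay lowest (-30.9 and -23.6), and WT 4 (13.5) and Sel1l-/- 4 (35.5) highest. The macrophage mean was lowest in WT 3 and WT 1 and highest in Sel1l-/- 4 as well. On the second component the WT arrays lay from -22.1 to -4.64 and the Sel1l-/- arrays from -0.943 to 23.9, without overlap. Immunoglobulin transcripts stood out in 1 mouse of each group. Jchain read 9.13 in WT 2 and 7.70 in Sel1l-/- 4, against 4.68 to 6.06 in the other 6 arrays, and Igkc 8.63 and 8.75, against 4.61 to 5.64.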
